A study of Mus musculus with 7 samples.

How the data were processed

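RNA from epididymal white adipose tissue of 17-week-old male mice was measured in 7 samples, 4 wild type and 3 aP2-XBP1 transgenic. Per the labels' protocols, total RNA was extracted with TRIzol and purified on columns, and samples were hybridised only with an RNA integrity number above 8.0. Labelled cDNA was made from 100 ng of total RNA without removal of ribosomal RNA. The platform table describes the array as Affymetrix Mouse Gene 1.0 ST, with 1 colour per array.

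The authors deposited 1 table of log2 expression values, which per the submitters' processing notes were made with RMA, a method that corrects background, normalizes arrays to each other by quantiles and summarises the probes of a probe set. The version of RMA, the probe set definition and any filter are not given in the sources used here. Scanner files were not used, so background correction could not be varied. Because RMA brings the arrays to a common distribution, a shift of all genes in one genotype would not be seen in these values. The value table holds 35556 probe sets. All 7 of its columns were matched to samples by their labels, and 0 columns of sample values were left unused.

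Genes were named from the array's platform annotation, whose symbols can be old. Exactly 1 gene symbol belonged to 21789 probe sets, several symbols to 1621, and 12146 had none or were not listed. Tests used the 21789 probe sets, which stand for 19938 genes. Of these probe sets 21698 matched a RefSeq gene table by Entrez identifier, and 0 symbols needed an update. No genome build is named in the sources, so no coordinates are given.

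Samples were grouped by the genotype in the labels. Differences, transgenic minus wild type, were fitted on the log2 values as deposited with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with genotype as the only term, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. A fold is 2 to the power of the log2 difference. Gene lists were tested with camera, which asks whether the members rank higher or lower than other genes, with a preset correlation of 0.01 and adjustment over the lists. Each gene entered lists by the probe set with the highest mean over all 7 samples. A list's members were also tested with the p adjusted over the list alone. The list score of a library is the mean log2 value of the members. For single values an exact two-sided permutation test used the absolute difference of the means over all 35 splits of the 7 libraries, whose smallest p is 0.0286.

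There were 34 lists with 706 entries, of which 648 were measured, for 629 distinct genes. They covered ER protein folding and transport, other stress pathways, adiponectin assembly, fat and energy metabolism, and markers of other cell types that a fat pad can hold. The lists, the fit, the tests, the alternatives listed here and the rule for named genes were fixed before the data were examined. That rule named Xbp1, Fabp4 and Adipoq always. It took the 10 largest changes in each direction among passing genes with groups that do not overlap, leaving out predicted, microRNA, small nucleolar, olfactory and vomeronasal genes. With fewer than 5 passing in a direction, it took the 5 with the smallest p, said not to pass. In each list it took up to 4 passing members, or else up to 2 with the smallest p. Lists of the reproductive tract, sperm, seminal vesicle and ductal epithelium, and the division of the smooth muscle list, were added after the data were seen.

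Alternatives were a block for the replicate number (fitted with limma), another round of quantile normalization, arrays shifted to a common median, leaving out the dimmest probe sets, testing every row of the table, 1 probe set per gene, an intensity trend with a robust prior, array weights (statmod 1.5.0 was loaded), leaving out each library, an adjusted p of 0.1, a minimum of 1.5-fold, camera with an estimated correlation and fry. A fit with wild type replicate 2 as the only control, a fit with a covariate (the mean of Serpina1f, Spink8 and Defb42) and a permutation test of list scores were added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9 from tables read with pandas 2.3.3.

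The fit was tested on simulated data with the real means and 200 of the 21789 probe sets changed. Of probe sets changed by 0.5, 1, 2 and 3 on the log2 scale, 28%, 80%, 90% and 98% were recovered at the real spread of each probe set, with 8 false calls. The simulated noise was independent between probe sets, and 50 probe sets were changed at each size, the large ones included. These rates therefore do not describe the real fit, where Pdia6 differed by 1.03 with a limma adjusted p = 0.622. No pair of arrays held identical values, and at most 15.4% of probe sets agreed to the last digit in any pair, so each sample was counted once.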

Results

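Epididymal white adipose tissue, the visceral fat pad that lies against the epididymis and testis of male mice, was profiled in 7 samples, 4 of them wild type and 3 carrying an aP2-XBP1 transgene. The aP2 promoter is that of Fabp4, the fatty acid carrier of adipocytes, and XBP1 is a transcription factor of the unfolded protein response, the program that enlarges the folding capacity of the endoplasmic reticulum (ER). All animals were male C57BL/6J mice of 17 weeks on chow. Each sample was hybridised to 1 Affymetrix Mouse Gene 1.0 ST array, a 1-colour array with probes spread along each transcript. The deposited values are log2 expression after RMA for 35556 probe sets. Medians of the 7 arrays lay between 3.99 and 4.04, and the number of arrays limits the precision. They ran from 4.03 to 4.04 in wild type and from 3.99 to 4.01 in transgenic arrays. A small offset between arrays therefore goes together with genotype. Pairwise correlations of the arrays across probe sets ran from 0.973 to 0.996. The labels number the samples as replicates without saying that each came from a separate animal, so p-values measure the spread between these samples, which may be partly technical.

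The design holds a single comparison, transgenic against wild type fat. It asks which transcripts differ when XBP1 is overexpressed in fat, and the series title ties this to insulin sensitivity and to the assembly of adiponectin, an adipocyte hormone, into multimers.

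Xbp1 itself was higher in each of the 3 transgenic libraries than in each of the 4 wild type libraries. Its probe set (10374035) read 9.03 ± 0.13 (SD, n = 4) in wild type and 9.80 ± 0.17 (SD, n = 3) in transgenic fat, a 1.71-fold difference (log2 difference 0.77, SE 0.11). It ranked 2 of the 21789 probe sets by limma's p, with an adjusted p = 0.622, and an exact two-sided permutation test gave p = 0.0286, the smallest that 35 splits of 4 and 3 libraries allow. The probe set cannot separate the endogenous gene from a transgene or spliced from unspliced transcripts. Fabp4 (10497265), whose promoter drives the transgene, read 12.09 ± 0.23 (SD, n = 4) and 12.30 ± 0.05 (SD, n = 3), a difference of 0.22 (SE 0.13) with overlapping groups.

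Of single genes, 0 passed an adjusted p of 0.05 with limma in either direction, and the smallest adjusted p was 0.622. At an unadjusted p under 0.05, limma found 1050 probe sets higher and 679 lower in transgenic fat, where about 545 in each direction come by chance. After the arrays were shifted to a common median the same threshold gave 1900 higher and 446 lower. Groups did not overlap for 737 probe sets higher and 532 lower in transgenic fat, against 623 in each direction by chance (2.86%). The median difference of all probe sets was 0.01. Without wild type replicate 2, limma called 7 probe sets higher and 84 lower at adjusted p under 0.05, and with any other library left out it called 0. Wild type replicate 2 lay nearer to the transgenic mean for 83 of the 84 and for 7 of the 7, against 58.8% of all probe sets tested. This is partly by construction, since these calls end with that library in. Those lower include Serpina1f, Spink8 and Defb42, which are described below, so the calls cannot be read as effects of genotype.

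The 5 genes with the smallest p in each direction did not pass and are given as values. Besides Xbp1, the higher ones were Hcar1, the lactate receptor of adipocytes, at 7.01 ± 0.16 (SD, n = 4) and 7.80 ± 0.12 (SD, n = 3), Krt36 (difference 0.37), Pold2, a DNA polymerase delta subunit (0.40), and Lsm5, a component of U6 snRNP (0.68). Krt36 and Lsm5 were dim, at wild type means of 2.58 and 2.36, and the 2 brighter probe sets of Lsm5 differed by 0.04 and -0.07. The lower ones were the transcription factor Mef2a (-0.38), the actin-binding proteins Ccdc88a (-0.46) and Nexn (-0.92), Nrep (-0.44) and the dehydrogenase Bdh2 (-0.62). In all 10 genes every transgenic library lay beyond every wild type library.

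**Figure D1:**
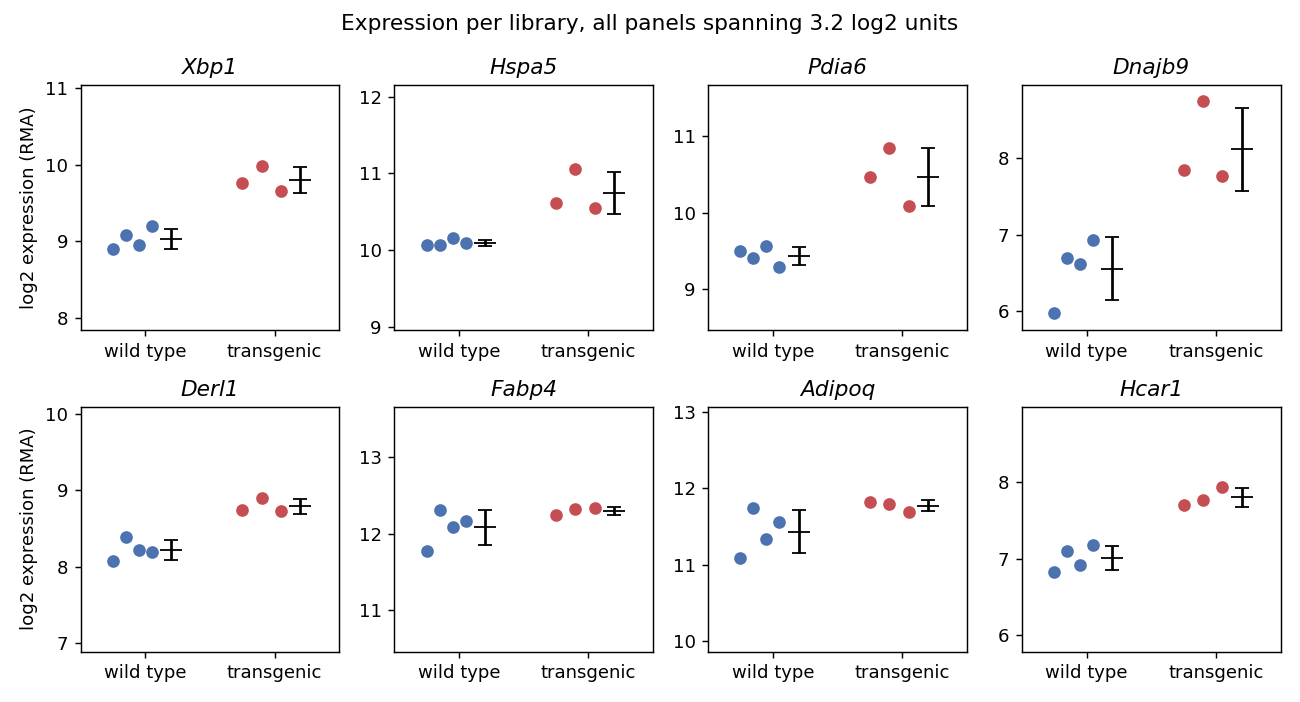
Log2 expression (y axis) of 8 genes in the 4 wild type (blue) and 3 transgenic (red) libraries, 1 point per library, with the group mean and SD as a bar beside the points. Transgenic points lie above all wild type points for Xbp1, Hspa5, Pdia6, Dnajb9, Derl1 and Hcar1, while the groups overlap for Fabp4 and Adipoq.

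Chaperones and folding enzymes of the ER were higher in transgenic fat. In the list ER chaperones and folding, 25 of 30 measured genes had a higher mean in transgenic fat, and 12 rose at a p adjusted over the list alone, against 0 adjusted over all genes tested. Hspa5 (10471586), the chaperone BiP, read 10.09 ± 0.04 (SD, n = 4) in wild type and 10.74 ± 0.28 (SD, n = 3) in transgenic fat, a 1.56-fold difference. Pdia6 (10394735), a protein disulfide isomerase, differed 2.04-fold (log2 difference 1.03, SE 0.18). The other 10 were Dnajb9, Dnajc3, Manf, Sdf2l1, Creld2, Hyou1, Txndc11, Sec63, Fkbp2 and Sil1, with log2 differences from 0.29 (Sil1) to 1.57 (Dnajb9). Dnajb9 (10400137), a co-chaperone of BiP, went from 6.55 ± 0.41 (SD, n = 4) to 8.12 ± 0.54 (SD, n = 3), a 2.96-fold difference. These 10, like Derl3 and the other members named beyond the 2 of smallest p per list, were chosen after their values were seen. Dnajc10, a reductase of the ER, had the lowest difference of the list, -0.49, and did not pass. The list's median difference was 0.24, and camera ranked it above other genes (adjusted p = 2.9e-08 with the preset correlation, adjusted p = 0.388 with an estimated correlation). The small p is not particular to genotype. Wild type replicate 3 grouped with transgenic replicates 1 and 2 gave a smaller one (camera adjusted p = 2.1e-11 with the preset correlation, median 0.19). The median difference was largest for the real grouping. Transgenic replicate 2 had the highest score of the list, 8.48, and without it the median difference was 0.11 and the call held (adjusted p = 1.4e-06).

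ER-associated degradation, which returns misfolded proteins to the cytosol, went the same way in 18 of 19 genes. In this list 8 genes rose at a p adjusted over the list alone, with 0 over all genes: Derl1, Os9, Syvn1, Derl3, Selenos, Edem1, Edem3 and Ubxn4. Derl1 (10428736), a channel component, read 8.22 ± 0.13 (SD, n = 4) and 8.79 ± 0.10 (SD, n = 3), 1.48-fold apart, and the lectin Os9 differed 1.46-fold. Derl3 had the largest difference, 1.17 (SE 0.29). The median difference was 0.35, with a camera adjusted p = 3.1e-09 (adjusted p = 0.388 with an estimated correlation). With wild type replicate 2 as the only control, an alternative added after the data were seen, the median difference was 0.19 and the call ended (adjusted p = 0.314).

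Other steps of the secretory pathway had smaller median differences. In the list of ER translocation and N-glycosylation 32 of 35 genes had a higher transgenic mean and 0 passed over the list alone. Its median difference was 0.14 (camera adjusted p = 6.2e-07; adjusted p = 0.388 with an estimated correlation), and 0.08 without transgenic replicate 2. Dpagt1, the first enzyme of the N-glycan precursor, differed by 0.52 and the oligosaccharyltransferase Stt3b by 0.62. ER-to-Golgi transport had 29 of 34 genes higher, 0 of them passing, with a median difference of 0.10 (camera adjusted p = 4.0e-05; adjusted p = 0.388 with an estimated correlation). Preb and the cargo receptor Surf4 both differed by 0.31. The score of this list was 7.87 in wild type replicate 2, close to the wild type mean of 7.88, against a mean of 7.99 in transgenic fat.

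Other arms of ER stress signalling were not called. In the PERK-ATF4 arm, the branch of amino acid supply and translation control, 10 of 23 genes had a higher and 13 a lower transgenic mean, with a camera adjusted p = 0.248. Psat1 rose (0.49), and Slc3a2 (-0.27), Slc7a5 (-0.51) and Shmt2 (-1.0) fell at a p adjusted over the list alone. Shmt2 read 6.20, 6.39 and 6.61 in wild type replicates 1, 3 and 4 but 5.63 in wild type replicate 2, against 5.13 to 5.29 in transgenic fat. Ddit3 (CHOP) and Atf4 differed by -0.03 and -0.10 with overlapping groups, and the sign for Ddit3 turned to 0.01 and 0.02 under quantile normalization and under shifting to a common median. Targets of IRE1-dependent mRNA decay had a median difference of 0.04 (adjusted p = 0.514), with 0 of 14 passing over the list alone. Of these Bloc1s3 differed by 0.32 and Pmp22 by 0.44. Hexosamine biosynthesis had a median difference of 0.14 (adjusted p = 0.755) and 0 of 10 passing, with Gfpt1, its rate-limiting enzyme, at 0.28 and Oga at -0.16.

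The adiponectin transcript itself did not pass the test. Adipoq (10434747) read 11.43 ± 0.28 (SD, n = 4) in wild type and 11.77 ± 0.07 (SD, n = 3) in transgenic fat, 1.26-fold apart (SE of the log2 difference 0.15, exact permutation p = 0.114), and the groups overlapped. Among 16 genes of adiponectin assembly and secretion 13 had a higher transgenic mean. Of these 2, Pdia6 and Hspa5, rose at a p adjusted over the list alone. Both also stand in the ER chaperone list, as do P4hb (0.19), Pdia3 (0.25) and Pdia4 (0.35). The call of this list is therefore not separate from that of the ER chaperones. The list's median difference was 0.18 (camera adjusted p = 0.00102; adjusted p = 0.388 with an estimated correlation). It was 0.10 without transgenic replicate 2 (adjusted p = 0.0017), and the call ended with wild type replicate 2 as the only control (0.14, adjusted p = 0.350).

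**Figure D2:**
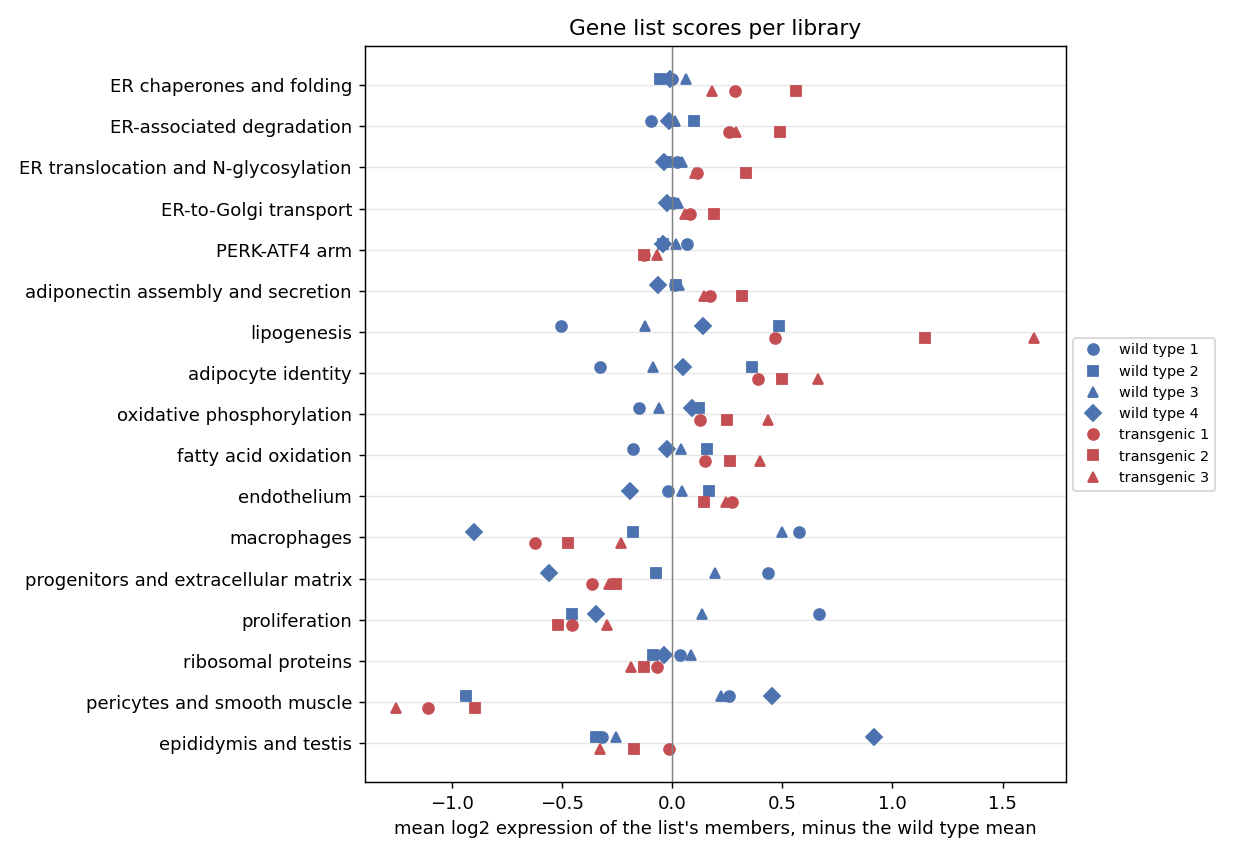
Score of 17 gene lists in each library, the mean log2 expression of the list's members minus the wild type mean (x axis); blue symbols are the 4 wild type and red symbols the 3 transgenic libraries. ER lists separate the genotypes, while for pericytes and smooth muscle wild type replicate 2 lies among the transgenic libraries.

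Wild type replicates 1, 3 and 4 carried transcripts that the other 4 libraries lacked. Serpina1f, Spink8 and Defb42, genes known from the epididymis, were noticed after the data were seen. Serpina1f read 10.70, 10.84 and 11.50 in wild type replicates 1, 3 and 4, against 2.74 in wild type replicate 2 and between 2.83 and 3.73 in the transgenic libraries. Genes of smooth muscle followed the same libraries. Myh11, the smooth muscle myosin heavy chain, read 10.92, 10.92 and 11.51 in wild type replicates 1, 3 and 4, 8.21 in wild type replicate 2 and 7.75 to 8.53 in transgenic fat. The list of pericytes and smooth muscle had 10 of 12 genes lower in transgenic fat, 0 of them passing over the list alone, with a median difference of -0.98 (camera adjusted p = 4.9e-05; adjusted p = 0.388 with an estimated correlation). Acta2 differed by -1.25 and Des by -2.05. With wild type replicate 2 as the only control the list's median difference was -0.06 (adjusted p = 0.345). Across libraries, wild type replicate 2 correlated with the transgenic libraries at 0.9938 or above and with other wild type libraries at no more than 0.989.

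**Figure D3:**
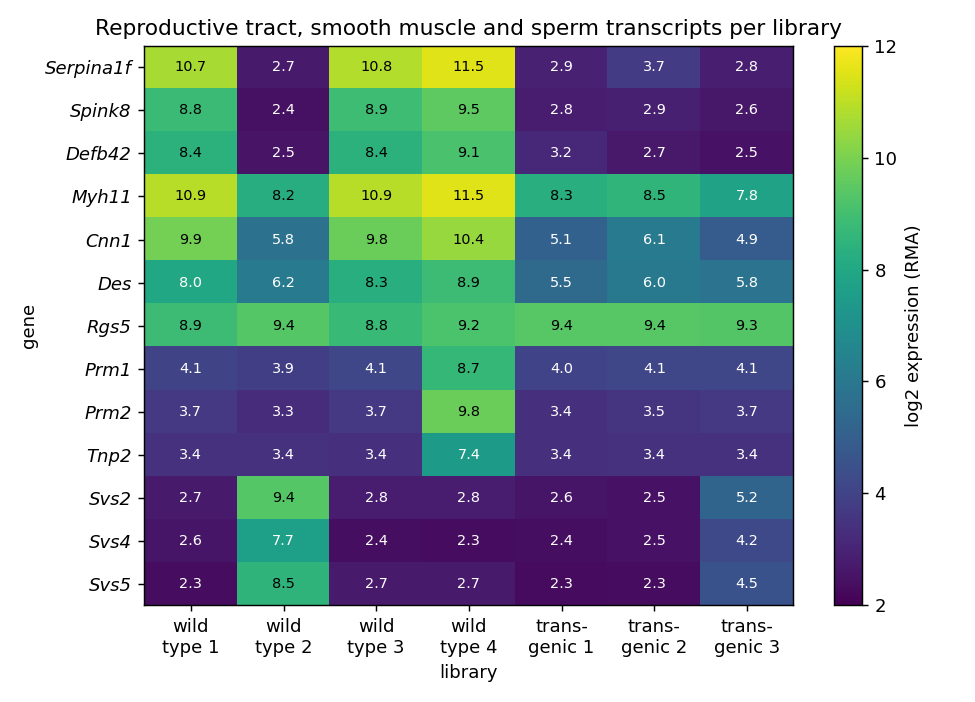
Log2 expression (colour and printed value) of 13 genes of the male reproductive tract, smooth muscle, pericytes (Rgs5) and sperm in each of the 7 libraries. Wild type replicates 1, 3 and 4 stand apart for Serpina1f, Spink8, Defb42, Myh11, Cnn1 and Des, wild type replicate 4 for Prm1, Prm2 and Tnp2, and wild type replicate 2 for Svs2, Svs4 and Svs5.

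Lipogenic enzymes had the largest median difference among the lists called higher, beside the tract transcripts in 3 wild type libraries described above. All 19 measured genes had a higher transgenic mean and 14 rose at a p adjusted over the list alone, with 0 over all genes. Srebf1, the transcription factor of lipogenesis, read 7.85 ± 0.26 (SD, n = 4) and 8.42 ± 0.16 (SD, n = 3), a 1.49-fold difference. Acaca, acetyl-CoA carboxylase, differed 3.38-fold, Acly, ATP citrate lyase, 3.58-fold and Fasn, fatty acid synthase, 2.87-fold. The groups overlapped for Acaca and Fasn, with Fasn at 11.37 in wild type replicate 2 and 11.15 in transgenic replicate 1. Acly did not overlap but ran from 9.12 to 11.42 within transgenic fat. The list's median difference was 1.00 (camera adjusted p = 1.2e-11; adjusted p = 0.388 with an estimated correlation). Its score in wild type replicate 2, 9.29, lay above that of transgenic replicate 1, 9.27. Against wild type replicate 2 alone the median difference was 0.47. With the tract marker score as a covariate it was 0.50 (camera adjusted p = 0.00103). That score was 9.31 to 10.05 in wild type replicates 1, 3 and 4 and 2.57 to 3.10 elsewhere. Both fits therefore rest mostly on wild type replicate 2 as the control, and the second is not separate evidence.

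Adipocyte and mitochondrial genes went the same way with smaller differences. All 24 adipocyte identity genes had a higher transgenic mean, with 0 passing over the list alone and a median difference of 0.46 (camera adjusted p = 1.2e-10; adjusted p = 0.388 with an estimated correlation). Dgat1, a triglyceride synthesis enzyme, differed by 0.85 and Slc2a4, the insulin-responsive glucose transporter, by 0.83. Among the wild type libraries this score was highest in replicate 2, at 10.53 against 9.84 to 10.22 in the others. The median difference was 0.10 against that library alone (adjusted p = 0.45) and 0.14 with the tract marker score as a covariate (adjusted p = 0.111). Oxidative phosphorylation had 31 of 31 genes higher, with Sdhd at 0.38 and Cox4i1 at 0.22. None passed alone, and the median difference was 0.26 (camera adjusted p = 1.8e-11; adjusted p = 0.388 with an estimated correlation) and 0.14 against wild type replicate 2 alone (adjusted p = 0.0328). In the list fatty acid oxidation 15 of 18 genes were higher and Cpt2 (0.61) and Acads (0.49) rose at a p adjusted over the list alone. The list's median difference was 0.36 (camera adjusted p = 5.8e-06; adjusted p = 0.388 with an estimated correlation), and 0.12 against wild type replicate 2 alone (adjusted p = 0.590).

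Camera calls of 4 further lists lay closer to the threshold. Insulin signalling had 14 of 18 genes higher, with Hk2 at 0.60, and a median difference of 0.18 (camera adjusted p = 0.042; adjusted p = 0.541 with an estimated correlation). Brown and beige adipocyte genes had 12 of 15 higher, led by Cidea (0.76) and Cox8b (1.18), with a median of 0.10 (adjusted p = 0.0185; adjusted p = 0.458 with an estimated correlation). Hypoxia and glycolysis had 15 of 21 higher, with Ldha at 0.40 and Vegfa at 0.49, and a median of 0.14 (adjusted p = 0.0498; adjusted p = 0.50 with an estimated correlation). The circadian clock list had 13 of 16 higher, with Dbp at 0.52 and Arntl at -0.26, and a median of 0.19 (adjusted p = 0.0356; adjusted p = 0.541 with an estimated correlation). In these 4 lists 0 genes passed over the list alone, and against wild type replicate 2 alone all 4 calls ended, with medians of -0.06, 0.05, 0.13 and -0.18. Shifting the arrays to a common median also ended the calls of insulin signalling (adjusted p = 0.126), hypoxia and glycolysis (0.153) and the circadian clock (0.116), and array weights those of brown and beige adipocytes (0.108) and hypoxia and glycolysis (0.154). Quantile normalization again ended those of insulin signalling and hypoxia and glycolysis (both 0.118), and leaving out the dimmest probe sets those of insulin signalling (0.0508) and brown and beige adipocytes (0.0549). The calls of insulin signalling and the circadian clock also ended without any 1 of wild type replicates 1, 3 and 4 and transgenic replicates 1 and 3. That of hypoxia and glycolysis ended without wild type replicate 1, 3 or 4 or transgenic replicate 3, and that of brown and beige adipocytes without wild type replicate 1 or 4 or transgenic replicate 2. The median of insulin signalling was 0.11 without wild type replicate 1 and that of brown and beige adipocytes 0.05 without transgenic replicate 2. For hypoxia and glycolysis it was 0.255 without transgenic replicate 1, and for the circadian clock 0.32 without wild type replicate 2 and 0.29 with array weights. In cholesterol biosynthesis 13 of 19 genes were higher and Sc5d rose (0.60) over the list alone, with Lss at 1.02, but the list was not called (median 0.15, adjusted p = 0.0652). The median of cholesterol biosynthesis was 0.02 without transgenic replicate 3 (adjusted p = 0.624), while the list was called without wild type replicate 1 (0.0428) or transgenic replicate 1 (0.00122), with every probe set tested (0.0391) and with the tract marker score as a covariate (0.0169).

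Markers of other cell types in the fat pad varied among the wild type libraries. Macrophage genes were lower in 19 of 22 cases, and Cd9 fell (-0.78) over the list alone while Cd163, a marker of resident macrophages, differed by 0.89. The macrophage score was 8.54 and 8.47 in wild type replicates 1 and 3 but 7.79 and 7.07 in replicates 2 and 4, against 7.35 to 7.74 in transgenic fat. The list's median difference was -0.25 (camera adjusted p = 0.00416; adjusted p = 0.562 with an estimated correlation). The call of macrophages ended without wild type replicate 1 (median -0.15, adjusted p = 0.0769), wild type replicate 3 (-0.14, 0.132) or transgenic replicate 1 (-0.19, 0.0504), and against wild type replicate 2 alone (-0.17, 0.590). The median of macrophages was -0.51 without wild type replicate 4 and -0.53 with array weights. Genes of progenitors and extracellular matrix were lower in 16 of 21 cases, with Postn at -1.05 and Tgfb1 at -0.48, 0 passing over the list alone and a median of -0.29 (camera adjusted p = 0.00216; adjusted p = 0.50 with an estimated correlation). That median was -0.14 without wild type replicate 1 and -0.49 without wild type replicate 4. Proliferation genes were lower in 22 of 23 cases, with Bub1 at -0.82 and Top2a at -0.95, 0 passing over the list alone and a median of -0.38 (camera adjusted p = 1.0e-06; adjusted p = 0.50 with an estimated correlation). Its median was -0.18 without wild type replicate 1, and 0.02 against wild type replicate 2 alone (adjusted p = 0.887). Endothelial genes were higher in 15 of 16 cases, with Gpihbp1 at 0.49 and Pecam1 at 0.20, 0 passing over the list alone and a median of 0.20 (camera adjusted p = 0.000116; adjusted p = 0.388 with an estimated correlation). Against wild type replicate 2 alone the median of the endothelium list was 0.06 (adjusted p = 0.590). Ribosomal protein genes were lower in 23 of 24 cases, with Rpl19 at -0.20 and Rpl8 at -0.18, 0 passing over the list alone and a median of -0.13 (camera adjusted p = 2.0e-09; adjusted p = 0.388 with an estimated correlation). It was -0.04 against wild type replicate 2 alone (adjusted p = 0.0383).

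The remaining lists were not called by camera with all libraries in. Inflammatory cytokines and chemokines had a median difference of -0.12 (adjusted p = 0.329), with Cxcl12 at -0.21 and Ptgs2 at -5.08; Ptgs2 read 4.98 in wild type replicate 2 and above 11 in the other wild type libraries. T and NK cell genes had a median of -0.03 (adjusted p = 0.331), with Foxp3 at 0.08 and Il7r at -1.35. B and plasma cell genes had 0.04 (adjusted p = 0.730), with Prdm1 at -0.45 and Ms4a1 at 0.52. Neutrophil and mast cell genes had 0.07 (adjusted p = 0.268), with Ms4a2 at 0.13 and Retnlg at 0.32. Mesothelial genes had 0.28 (adjusted p = 0.544), with Krt19 at -0.79 and Efna5 at 0.61. The fixed list of epididymis and testis genes had a median of 0.05, a mean of -0.17 and an adjusted p = 0.992, with Lcn5 at 0.36 and Spint5 at -0.14. Blood cell genes had 0.10 (adjusted p = 0.166), with Alas2 at 0.57 and Epb42 at 0.16. Skeletal muscle genes had a median near 0 but a mean of -0.25 (adjusted p = 0.496), and Acta1 fell (-2.01) over the list alone, with Tnnc2 at -1.19. Immediate-early genes had a median of 0.03 and a mean of -0.07 (adjusted p = 0.544), with Egr2 at -0.82 and Nr4a1 at 0.41. Cytosolic heat shock genes had -0.01 (adjusted p = 0.553), with Hspa8 at -0.19 and Hspe1 at 0.24. Milk protein and mammary genes had -0.05 (adjusted p = 0.130), with Elf5 at -0.95 and Krt14 at -0.26. With 1 library left out, camera called blood higher (0.13, adjusted p = 0.0434) and cytosolic heat shock lower (-0.11, adjusted p = 0.0396) without wild type replicate 1. It called milk proteins and mammary markers lower without wild type replicate 2 (adjusted p = 0.0308) or transgenic replicate 2 (0.0392). Among these 11 lists Acta1 was the 1 member that passed over its list alone.

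Over the 34 lists camera with its preset correlation called 14 higher and 5 lower in transgenic fat. With an estimated correlation it called 0, the smallest adjusted p being 0.388. The rotation test fry called 0 lists as moving one way on balance (smallest adjusted p = 0.129). It called 3 as changing in either direction, namely ER chaperones (adjusted p = 0.0397), ER-associated degradation (0.0397) and adiponectin assembly (0.0385). The adiponectin list shares Hspa5, Pdia6, P4hb, Pdia3 and Pdia4 with the ER chaperone list. Scores of 9 lists were higher in every transgenic than in every wild type library, and that of the PERK-ATF4 arm was lower. Wars, with the largest drop of that arm (-1.41), was high in the libraries with tract transcripts. It read 9.72, 8.94 and 9.58 in wild type replicates 1, 3 and 4. In wild type replicate 2 it read 7.71, against 7.43 to 7.66 in transgenic fat. An exact permutation test of the list scores, added after the data were seen, gave an adjusted p of 0.139 at the lowest. List scores of ER chaperones were 7.92 ± 0.05 (SD, n = 4) in wild type and 8.26 ± 0.20 (SD, n = 3) in transgenic fat.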

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

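The lists of tract, sperm and seminal vesicle transcripts in this part, and the fits with wild type replicate 2 as the only control or with the tract marker score, were chosen after the results were seen; the ductal epithelium and pericyte tests were set before their own values were seen but after the smooth muscle pattern was noticed.

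Among the 4 wild type libraries, a value stood apart when its gap to the nearest of the others, as a share of the group's range, exceeded Dixon's critical value, and this held for 16 of 127 results tested. Of the 16, 6 are genes named after their values were seen (Serpina1f, Spink8, Defb42, Svs2, Prm2 and Ddit3), so the 16 are not set against chance. Without such genes 10 of 111 results stood apart, 6 of them by wild type replicate 2, where chance gives this in about 1 in 20 groups; these results are not independent, and some genes among them were chosen by their p values.

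Wild type replicate 2 was low, while wild type replicates 1, 3 and 4 were high, for Serpina1f (2.74), Spink8 (2.45), Defb42 (2.51), Ptgs2 (4.98), Acta2 (10.72), Tnnc2 (3.69), Bub1 (2.63) and the score of pericytes and smooth muscle (7.15). A candidate explanation is tissue of the male reproductive tract in wild type replicates 1, 3 and 4; 12 epithelial genes scored 0.22 higher in the lowest of these 3 libraries (4.39) than in the highest of the other 4 (4.17); 1 of the 12 is in a fixed list and 4 lay above the array median in the other 4 libraries. Of the 12, 8 were lower in transgenic fat, such as Epcam (5.90 to 6.95 in the 3 libraries, 5.10 to 5.86 in the other 4) and Cdh1 (5.75 to 6.69 against 4.73 to 5.29). Elf3 was 0.36 higher, and Krt15, Foxi1 and Atp6v1b1 did not follow either. Nor did the epididymal genes Lcn5, Gpx5, Rnase9 and Adam7 of a fixed list (2.05 to 3.60 against 1.90 to 4.69, the highest being Adam7 in transgenic replicate 1). Transgenic replicate 1 also read highest for Lcn8 (4.14), Lcn9 (3.60) and Cst11 (3.52) of that list. The other libraries read at most 3.09, 2.72 and 3.08 for these. Serpina1f, Spink8 and Defb42 were listed as markers of the distal epididymis and vas deferens, and the fixed list was not divided by region. More blood vessel wall in wild type fat would raise pericyte genes too. The 5 pericyte genes had a median difference of -0.016, against -1.53 for 7 smooth muscle genes. That median is the value of Notch3, which like Kcnj8 (0.03) varied little over the libraries. Pdgfrb (-0.36) and Cspg4 (-0.19) were lower in transgenic fat and Rgs5 (0.34) was higher. With genes that disagree or hardly vary, the median cannot exclude this explanation. Whether genotype contributes stays open. Of the 3 transgenic libraries 0 carried Serpina1f, Spink8 and Defb42 at the levels of wild type replicates 1, 3 and 4. The labels do not say how the pad was dissected.

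Wild type replicate 2 was also high for Svs2 (9.36), a secretory protein of the seminal vesicle, and for Sdhd (8.35). Wild type replicate 4 was high for the sperm protamine Prm2 (9.76) and for the epididymis and testis score (4.38), and low for Cxcl12 (7.45) and Ddit3 (5.16). Wild type replicate 1 was low for Cidea (3.81) and high for Spint5 (3.26). No explanation of these values was tested.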

How the results depend on the processing

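The fits with wild type replicate 2 as the only control and with the tract marker score as a covariate were added after the results were seen; all other settings here were planned. Xbp1 was higher in transgenic fat under every setting, with a log2 difference of 0.68 to 0.84 when each library was left out in turn. ER chaperones and folding had a median difference of 0.11 to 0.33, and adiponectin assembly and secretion of 0.10 to 0.24, with each library left out, and both calls held in each of those fits. Leaving out a library gave 10 to 14 gene lists higher and 4 to 6 lower, and 0 to 7 probe sets higher and 0 to 84 lower, where all calls of probe sets came from the fit without wild type replicate 2. Over all settings, 503 values of lists and 1543 of genes kept their direction and side of the threshold, 88 values of lists lost their call, 8 of lists and 11 of genes gained one and 46 of lists and 17 of genes turned their sign or the direction of their test. Leaving out the dimmest probe sets, which left fewer tests, gave a smallest adjusted p = 0.466 and still 0 genes.

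Camera with an estimated correlation and fry each called 0 gene lists higher and 0 lower, against 14 and 5; ER chaperones and folding kept its median of 0.239 with adjusted p = 0.388 and 0.176, and adiponectin assembly and secretion its 0.182 with adjusted p = 0.388 and 0.129. An estimated correlation above the preset widens the error of a list's mean, as the test is built. It was 0.339 for ER chaperones but only 0.023 for adiponectin assembly, against the preset 0.01. For the PERK-ATF4 arm it was -0.016, and camera's adjusted p still rose from 0.248 to 0.457. The wider error is therefore not the whole reason. With an estimated correlation camera also takes its p from a wider reference distribution, set by the small number of libraries. How much each part contributes was not tested. With wild type replicate 2 as the only control, 1 library assumed to vary like the others, camera called 4 lists higher and 2 lower, and adiponectin assembly and secretion had a median of 0.140 (adjusted p = 0.350, against 0.00018 to 0.013 over the planned fits with the preset correlation). With the tract marker score as a covariate, camera called 8 lists higher and 4 lower. Of the 19 calls, 10 held, 7 ended and 2 turned. That score was 9.31 to 10.05 in wild type replicates 1, 3 and 4 and 2.57 to 3.10 elsewhere. The genotype term therefore rests mostly on wild type replicate 2 against transgenic fat. Under this covariate limma called 0 genes higher and 3 lower, namely Svs1, Svs6 and Sva, named after their values were seen. Svs1 and Svs6 read 5.13 and 4.50 in wild type replicate 2, against at most 2.58 and 2.425 in any other library. Why that library was high was not tested.

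The replicate numbers showed no clear pairing of the samples. Libraries of the same number correlated at -0.139, -0.0946 and 0.0577 in their deviations from the group means. Of the 3 numbers 1 had its own partner as the best match. With so few libraries these values cannot exclude a pairing, and the labels state none. With the replicate block limma called 0 genes (smallest adjusted p = 0.495) and camera 10 lists higher and 5 lower, so that 4 of the 19 calls ended. Wild type replicate 4 has no transgenic partner and adds nothing to the difference under this block. Under this block RIDD target transcripts turned to a median of -0.0311, B and plasma cells to -0.0060 and cytosolic heat shock to 0.00012.

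The other turned values belong to results that passed no threshold, except where said. With quantile normalization again they were Ddit3 (0.0128), hexosamine biosynthesis (0.135) and epididymis and testis (0.0681), the last pair by the direction of the test and not of the median. Arrays shifted to a common median gave Ddit3 0.0153, and turned the test for mesothelium (median 0.324) and epididymis and testis (0.0931). Leaving out the dimmest probe sets gave B and plasma cells -0.0563 and epididymis and testis -1.02, and array weights gave B and plasma cells -0.0326. By fry, epididymis and testis (0.0524) went lower. With each library left out, the values that turned in at least 1 fit ran from -0.0215 to 0.178 for hexosamine biosynthesis, -0.0946 to 0.0670 for T and NK cells, 0.0935 to 0.531 for mesothelium, -0.0179 to 0.0812 for epididymis and testis, -0.0492 to 0.0593 for immediate-early genes, -0.0311 to 0.0587 for RIDD target transcripts, -0.0060 to 0.0957 for B and plasma cells, -0.109 to 0.0228 for cytosolic heat shock, -0.0789 to 0.0396 for Ddit3 and -1.89 to 0.657 for Svs2.

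Only wild type replicate 2 as control turned the genes Fabp4 (-0.0097), Tnnc2 (0.393), Bub1 (0.102), Atf4 (0.128), Prm2 (0.275), Spink8 (0.317), Serpina1f (0.411) and Defb42 (0.269). Among lists it turned RIDD target transcripts (-0.0047), hexosamine biosynthesis (-0.0414), inflammatory cytokines and chemokines (0.0416), T and NK cells (0.107, now called higher), mesothelium (-0.351), skeletal muscle (0.0528) and milk proteins and mammary markers (0.0144). Lists called before that turned here were insulin signalling (-0.0551), hypoxia and glycolysis (0.126, by the direction of the test), proliferation (0.0248) and circadian clock (-0.179), and none of these 4 was called. The tract marker score as a covariate turned Tnnc2 (0.293), Bub1 (0.0174), Atf4 (0.0967), Prm2 (0.512) and Serpina1f (0.0211), which enters that score. It also turned RIDD target transcripts (-0.0233), hexosamine biosynthesis (-0.0235), insulin signalling (-0.0419), inflammatory cytokines and chemokines (-0.0072, by the direction of the test), T and NK cells (0.0636), mesothelium (-0.229), skeletal muscle (0.0458), cytosolic heat shock (0.0338), milk proteins and mammary markers (0.0159) and circadian clock (-0.133, called lower). The cause was not tested.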

Other observations

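The slopes over the wild type libraries and the comparisons of lipogenic with adipocyte genes in this part were chosen after the results were seen, as were the sperm and seminal vesicle lists; the splits of the libraries were planned.

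Transcripts of late spermatids were high in a single library. Wild type replicate 4 read 8.65 for Prm1, 9.76 for Prm2, 7.45 for Tnp2 and 8.90 for Smcp, and its score over 9 such genes was 7.29, against 2.95 to 3.24 in the other 6 libraries; 4 of the 9 are in the fixed epididymis and testis list. Secretory genes of the seminal vesicle were high in wild type replicate 2, with Svs2 at 9.36, Svs5 at 8.48 and Svs4 at 7.66. They read 5.22, 4.52 and 4.22 in transgenic replicate 3 and below 2.8 in the other 5 libraries. The score over 8 such genes, 0 of them in a fixed list, was 6.33 in wild type replicate 2 and 3.36 in transgenic replicate 3.

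The real split called 0 genes, a count that each of the 35 of 35 splits reaches by construction, so the splits say nothing on single genes and chance cannot be excluded. The highest other split called 224 and set wild type replicates 1, 3 and 4 against the other 4 libraries, which points to a structure of the samples. For gene lists the real split called 19 and 2 of 35 splits gave as many, so chance cannot be excluded; the highest other, 22, was again wild type replicates 1, 3 and 4 against the rest. With wild type replicate 2 as the only control, camera called 4 lists higher and 2 lower.

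ER chaperone and ER degradation genes were higher in transgenic fat, and a smaller share of fat cells in the wild type libraries is a candidate explanation. If it held, the ER score would follow the adipocyte score among the wild type libraries with a slope of 0.741 for chaperones and 0.743 for degradation. The slope for chaperones was -0.11 and ran from -0.24 to 0.01 with each library left out, which argues against fat cell share as the whole cause. The slope for degradation was 0.27 (0.22 to 0.29 with each left out), also below what the explanation needs. Both slopes rest on few libraries, and wild type replicates 1, 3 and 4 among them carried tract transcripts, so they may not measure fat cell share alone. A genotype effect remains a hypothesis, found and examined on the same 7 libraries.

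The list of lipogenesis was called higher in transgenic fat, and a smaller share of fat cells in the wild type libraries is a candidate explanation. Among the wild type libraries the lipogenesis score followed the adipocyte score, over 21 genes outside the lipogenesis list, with a slope of 1.48 (1.33 to 1.78 with each library left out), against the 2.34 that would explain the whole difference. The lipogenesis minus adipocyte score differed by 0.62 between genotypes (pooled SD 0.342; exact permutation p = 0.0857) and by 0.39 without transgenic replicate 3, and transgenic replicate 1, at -1.32, lay within the wild type range of -1.58 to -1.265. The lipogenesis score of transgenic replicate 1 also lay below that of wild type replicate 2 (difference -0.020). Fat cell share and genotype therefore cannot be told apart for this list, with so few libraries to set the slope.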
